A study of Danio rerio with 9 samples.

How the data were processed

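Whole brains from 9 zebrafish were measured, 3 from each of 3 groups: tp53 mutant animals with ptch1 disrupted by CRISPR and a tumor, tp53 heterozygous animals with ptch1 disrupted and a tumor, and tp53 mutant controls. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries. Replicate numbers are names that follow the order of the labels and pair no animals across groups.

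The table of whole-number counts per Ensembl gene was used as deposited. The submitters' processing notes name cutadapt 1.16, STAR 2.7.9a, DESeq2 1.32.0 and the genome build GRCz11. The role of each tool, the program that assigned reads to genes and the annotation release are not given in the sources used here. The deposited count table held 25001 genes, the smallest with a total of 6 counts, and no entry without a gene. The authors also deposited 4 comparison tables with log2 fold changes and p-values adjusted for multiple tests, whose column names are those of DESeq2 output. In 1 of these the sign was turned so that positive values mean higher in the tumor, which was checked by its correlation of 0.959 with the fold changes from the counts. A second deposited count table held the 3 mutant tumor libraries again beside 4 columns that match no sample of the series, and these 4 columns were not used. The authors' table that compares ptch1 tumors with the tumor type labelled NRAS was therefore described as deposited and not refitted. It has no column of mean counts, so the planned minimum on mean counts for naming genes from it could not be applied.

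Gene names were taken from a reference table of Ensembl gene names, which named 23117 of the 25001 genes (92.5%), 11711 of them in capitals after the human gene. Several zebrafish copies of a gene can share such a name, and their Ensembl identifiers are then given. Fixed gene lists, 29 in number with 570 symbols, were matched to these names, and 38 symbols had no match. Gene length and GC content were not analysed here.

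Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr at its default settings, which left 21607 genes, and libraries were scaled by TMM. All 9 libraries entered 1 quasi-likelihood fit (glmQLFit with robust estimation), each comparison was a contrast tested with glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. The SE of a log2 fold change was derived from the F statistic. Gene lists with at least 5 tested genes (28 of the 29) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. CPM are counts scaled to the TMM-adjusted library, and log2 CPM used a prior count of 2. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts a 95% counting interval was given.

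The fixed lists, the 3 comparisons, their tests, the rule for naming genes and all alternatives except the removal of the 4 most abundant features were set before the data were examined. The rule names PTCH1, TP53, PTCH2, GLI1, cdkn1a and mdm2 always, the 6 largest rises and 6 largest falls per comparison among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a clone name, and up to 4 genes of each list by adjusted p. From the authors' table it names the first 4 genes of each list by adjusted p and the 6 largest rises and falls.

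Depth ran from 16227965 to 26455444 counts per library, and replicates varied with a biological coefficient of variation of 28.6%. The analysis was tested on simulated data drawn from the real means and library sizes. Of genes changed 2-fold, 38.8% were recovered for mutant tumors against controls (21290 genes tested), 26.9% for heterozygous tumors against controls (21285 genes) and 26.9% between the tumor groups (21283 genes). Of genes changed 4-fold, 71.2, 81.8 and 74.2% were recovered in the same order, and 6, 0 and 1.5% of those changed 1.5-fold. False calls made up 6.7, 2.6 and 6.4% of the calls with edgeR and 25.6, 25.5 and 31.5% with DESeq2. Only 66 or 67 genes were changed at each fold, and edgeR called 90, 78 and 78 genes in the same order. Many more genes were called in the real comparisons, so these shares do not give the power of those comparisons.

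The alternatives were DESeq2 size factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the DESeq2 test, fits of only the groups compared, removal of 382 mitochondrial and ribosomal RNA features, removal of the 4 most abundant features, each library left out in turn, and for gene lists camera with an estimated correlation and fry. Agreement of the comparisons that share the controls was set beside 20 simulations of unchanged groups.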

Results

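Total RNA was sequenced from 9 whole zebrafish brains, each from a different animal, in 3 groups of 3. The tp53 mutant tumor brains and the tp53 heterozygous tumor brains came from animals in which ptch1, the receptor that restrains Sonic hedgehog (SHH) signaling, had been disrupted by CRISPR. The control brains came from tp53 mutant animals without this disruption. The heterozygous animals were 7 weeks old, the mutant tumor animals (replicates 1, 2 and 3) were 7, 8 and 4 weeks old, and the controls were 1 year old. Age therefore differed in the same way as tumor status, and neither tumor group had an age-matched control. No tp53 heterozygous control was measured, so heterozygous tumors differed from the controls in tp53 genotype as well. Per library 24017 to 24524 genes had at least 1 count, and 21607 of the 25001 genes passed the filter on low counts. The 13 genes with a mitochondrial (MT-) name took 1.52 to 2.1% of the counts in tumor brains and 2.82 to 3.07% in controls. The 4 most abundant features took 10.4 to 12.7% of the counts in mutant tumor brains, 14.1 to 15% in heterozygous tumor brains and 17.1 to 17.9% in controls. P-values of single genes measure the spread between these animals. List p-values from camera compare the genes of a list with all other genes. At the preset correlation of 0.01 they are not a measure of the spread between animals. All fold changes are log2 values ± SE with n = 3 brains per group unless stated otherwise.

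The transcripts of both targeted genes were measured first. PTCH1 mRNA stood at 39.6 ± 3.43 CPM in mutant tumors, 41.9 ± 10.4 in heterozygous tumors and 40.5 ± 3.26 in controls (mean ± SD, n = 3 each). It did not pass the test, with a change of -0.03 ± 0.18 (adjusted p = 0.902) in mutant tumors and 0.05 ± 0.18 (adjusted p = 0.866) in heterozygous tumors. An mRNA count does not show whether a coding sequence is disrupted, so this level does not test the ptch1 label. TP53 mRNA was higher than in controls in mutant tumors (1.13 ± 0.20, adjusted p = 0.00284) and in heterozygous tumors (1.15 ± 0.20, adjusted p = 0.00443), and differed by 0.02 ± 0.19 (adjusted p = 0.958) between the tumor groups. Targets of both pathways followed. GLI1, the transcription factor at the end of the SHH pathway, stood at 23.81, 15.65 and 20.43 CPM in the mutant tumors, 8.22, 28.94 and 11.41 CPM in the heterozygous tumors and 10.17, 6.76 and 9.34 CPM in the controls. Its change did not pass the edgeR test in mutant tumors (1.19 ± 0.43, adjusted p = 0.0572) or heterozygous tumors (0.89 ± 0.43, adjusted p = 0.164), and without heterozygous tumor replicate 2 the latter was 0.15, while the authors' deposited table gave 1.05 with an adjusted p of 0.0191 for the mutant tumors. PTCH2, a second patched receptor and SHH target, was lower in heterozygous tumors than in controls (-1.49 ± 0.34, adjusted p = 0.0158), and in mutant tumors it changed by -0.69 ± 0.34 (adjusted p = 0.141). The PTCH2 call was lost without control replicate 1 or 3, with adjusted p up to 0.0567 and fold changes from -1.78 to -1.17 over left-out libraries. The cell-cycle inhibitor and p53 target cdkn1a rose in heterozygous tumors (2.09 ± 0.36, adjusted p = 0.00438) and in mutant tumors (1.12 ± 0.36, adjusted p = 0.0366). In mutant tumors the cdkn1a call was lost without mutant tumor replicate 3 or any 1 of the 3 controls, with adjusted p up to 0.13 and fold changes from 0.83 to 1.28. mdm2, which encodes the ligase that degrades p53, changed by -0.13 ± 0.14 (adjusted p = 0.499) in mutant tumors and by 0.11 ± 0.14 (adjusted p = 0.603) in heterozygous tumors.

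**Figure D1:**
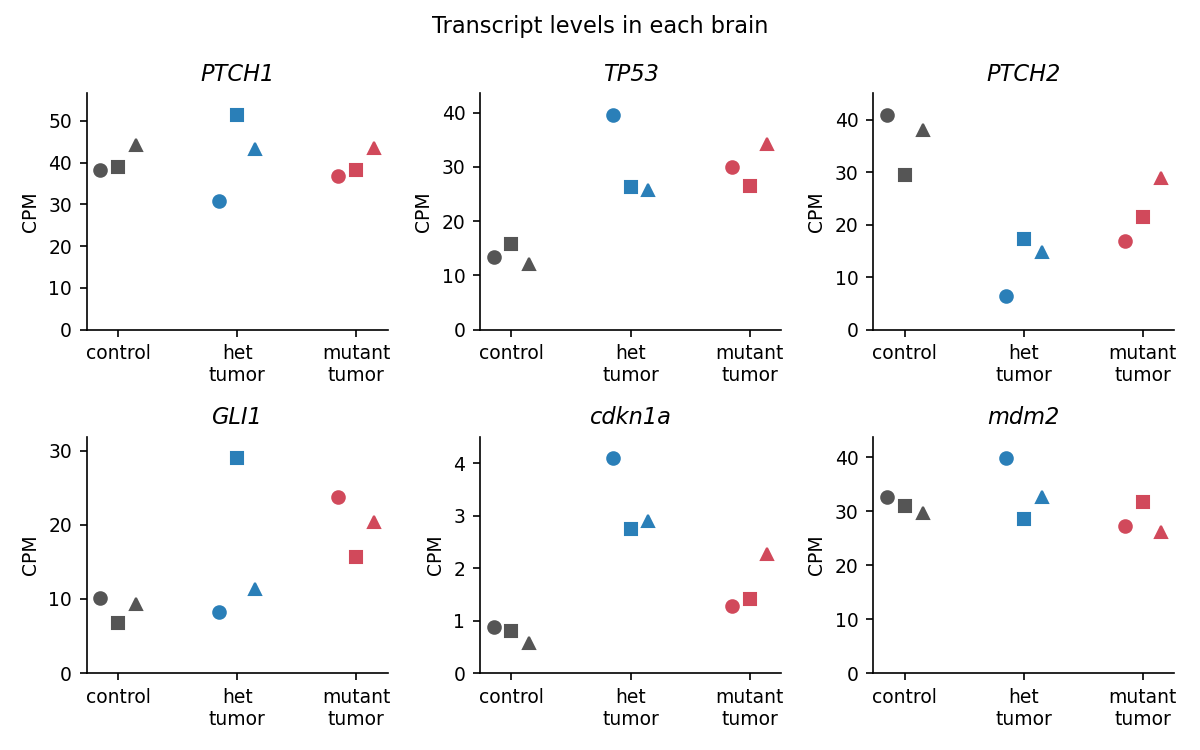
Transcript level (CPM) of PTCH1, TP53, PTCH2, GLI1, cdkn1a and mdm2 in each of the 9 brains, with circles, squares and triangles for replicates 1, 2 and 3. TP53 lay between 12.06 and 15.83 CPM in the 3 controls and between 25.81 and 39.56 CPM in the 6 tumor brains.

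The first comparison asked how tumor-bearing brains differed from control brains of the same tp53 genotype. Genes of cell division rose together in mutant tumors. Of the mitosis genes, 35 of 35 rose and 0 fell (35 and 0 adjusted over the list alone). Mitosis (G2/M) genes had a median log2 fold change of 4.60 (camera adjusted p = 2.83e-30, and adjusted p = 0.216 with an estimated correlation). Examples were the ubiquitin-conjugating enzyme of the anaphase UBE2C (4.37 ± 0.43, adjusted p = 0.000409), the cytokinesis motor KIF23 (5.43 ± 0.56, adjusted p = 0.000456) and the kinetochore gene CENPF (4.60 ± 0.49, adjusted p = 0.000463). Of the DNA replication genes, 33 of 33 rose and 0 fell (33 and 0 adjusted over the list alone). DNA replication (G1/S) genes had a median log2 fold change of 2.49 (camera adjusted p = 4.03e-23, and adjusted p = 0.216 with an estimated correlation). Leading genes were the helicase subunit MCM3 (2.60 ± 0.21, adjusted p = 0.000259), the histone mRNA binding protein slbp (2.42 ± 0.21, adjusted p = 0.000337) and the maintenance methylation factor UHRF1 (4.32 ± 0.43, adjusted p = 0.000413). Synaptic genes moved the other way, and 0 of 30 rose and 22 fell (0 and 23 adjusted over the list alone). Synaptic neuron genes had a median log2 fold change of -0.67 (camera adjusted p = 2.89e-11, and adjusted p = 0.216 with an estimated correlation). The kinase gene CAMK2A (-1.58 ± 0.13, adjusted p = 0.000311) and the AMPA receptor subunit GRIA2 (ENSDARG00000052765, -1.19 ± 0.12, adjusted p = 0.000409) were among these.

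Lists of SHH target genes and of progenitors of cerebellar granule neurons, from which SHH medulloblastoma arises, shifted upward, with part of their genes past the threshold. Of the SHH target genes, 7 of 15 rose and 2 fell (8 and 2 adjusted over the list alone). SHH target genes had a median log2 fold change of 0.69 (camera adjusted p = 0.0246, and adjusted p = 0.476 with an estimated correlation). MYCN, a driver of granule progenitor growth, rose to about the same level in all 3 mutant tumors (1.57 ± 0.10, adjusted p = 0.000194), and the cyclin gene CCND1 (2.94 ± 0.48, adjusted p = 0.00236) and the SHH transcription factor GLI2 (ENSDARG00000025641, 1.93 ± 0.41, adjusted p = 0.00771) rose as well, while the polycomb gene BMI1 (ENSDARG00000013076, -0.43 ± 0.10, adjusted p = 0.011) fell. PTCH1 and PTCH2, which belong to the SHH target list, did not pass. HHIP of the same list, chosen after its values were seen, was lower in mutant tumors. It stood at 28.48, 46.05 and 31.24 CPM in mutant tumors and 58.61, 51.19 and 58.48 CPM in controls. Of the ligands and transducers of the pathway, 6 of 18 rose and 0 fell (6 and 0 adjusted over the list alone). The list did not pass (camera adjusted p = 0.21), although the signal transducer SMO (2.21 ± 0.27, adjusted p = 0.000652) and the regulator GPR161 (ENSDARG00000058903, 3.25 ± 0.46, adjusted p = 0.00113) were higher. Of the granule neuron progenitor genes, 9 of 22 rose and 0 fell (9 and 1 adjusted over the list alone). Granule neuron progenitor genes had a median log2 fold change of 0.20 (camera adjusted p = 0.0133, and adjusted p = 0.216 with an estimated correlation). Leading genes were the transcription factors INSM1 (ENSDARG00000091756, 3.67 ± 0.31, adjusted p = 0.000313), nhlh2 (2.32 ± 0.23, adjusted p = 0.000409) and BARHL2 (1.76 ± 0.18, adjusted p = 0.000456). Of the immature neuron genes, 10 of 21 rose and 5 fell (10 and 7 adjusted over the list alone). Immature neuron genes had a median log2 fold change of 0.42 (camera adjusted p = 0.00118, and adjusted p = 0.476 with an estimated correlation). SOX4 (ENSDARG00000004588, 2.65 ± 0.23, adjusted p = 0.000322), SOX11 (ENSDARG00000077811, 2.61 ± 0.19, adjusted p = 0.000251) and STMN1 (ENSDARG00000004169, 4.32 ± 0.39, adjusted p = 0.000353) were among the rises. Without mutant tumor replicate 3 the mean log2 fold change of the immature neuron list was 0.5 in place of 0.81. Lists of mature cerebellar neurons shifted downward, again with part of their genes past the threshold. Of the mature granule neuron genes, 0 of 13 rose and 3 fell (0 and 2 adjusted over the list alone). Mature granule neuron genes had a median log2 fold change of -0.67 (camera adjusted p = 0.0252, and adjusted p = 0.538 with an estimated correlation). The synapse organizer CBLN1 (-1.03 ± 0.22, adjusted p = 0.00726) was first by adjusted p. This list call was lost without mutant tumor replicate 3 (adjusted p = 0.0783). Of the Purkinje cell genes, 2 of 19 rose and 8 fell (2 and 8 adjusted over the list alone). Purkinje cell genes had a median log2 fold change of -0.56 (camera adjusted p = 0.0227, and adjusted p = 0.476 with an estimated correlation). The glycolytic enzyme ALDOC (ENSDARG00000019702, -1.0 ± 0.18, adjusted p = 0.00329) and the calcium channel gene ITPR1 (ENSDARG00000074149, -1.47 ± 0.32, adjusted p = 0.00842) were among the falls.

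Several lists of immune, blood, stromal and glial genes shifted upward, as did the interferon response list, while the oligodendrocyte, endothelial, skin and retina lists did not pass. Of the interferon response genes, 15 of 22 rose and 0 fell (16 and 0 adjusted over the list alone). Interferon response genes had a median log2 fold change of 2.02 (camera adjusted p = 0.000862, and adjusted p = 0.538 with an estimated correlation). irf1b (2.06 ± 0.35, adjusted p = 0.00264) and the antiviral modifier isg15 (3.31 ± 0.72, adjusted p = 0.00801) were among the rises. The libraries overlapped on this list, whose mean log2 level over the controls was 2.41, 2.61 and 0.54 in mutant tumors and -0.86, 0.83 and 0.03 in controls, so mutant tumor replicate 3 lay below control replicate 2. Of the microglia and macrophage genes, 7 of 21 rose and 0 fell (7 and 0 adjusted over the list alone). Microglia and macrophage genes had a median log2 fold change of 0.46 (camera adjusted p = 0.00957, and adjusted p = 0.538 with an estimated correlation). The complement genes c1qc (2.61 ± 0.29, adjusted p = 0.000467), c1qa (2.47 ± 0.38, adjusted p = 0.0016) and c1qb (2.06 ± 0.34, adjusted p = 0.00221) led them. Of the lymphocyte genes, 6 of 15 rose and 0 fell (8 and 0 adjusted over the list alone). Lymphocyte genes had a median log2 fold change of 1.3 (camera adjusted p = 0.00307, and adjusted p = 0.216 with an estimated correlation), with the recombinase RAG1 (4.83 ± 0.58, adjusted p = 0.000595), a gene of immature lymphocytes, at 6.18, 2.74 and 10.09 CPM in mutant tumors against 0.24, 0.27 and 0.13 CPM in controls. Of the neutrophil genes, 4 of 7 rose and 0 fell (6 and 0 adjusted over the list alone). Neutrophil genes had a median log2 fold change of 2.71 (camera adjusted p = 0.0375, and adjusted p = 0.476 with an estimated correlation). MMP9 (2.66 ± 0.37, adjusted p = 0.00113) was first by adjusted p. The call for the list did not hold without control replicate 3 (adjusted p = 0.0547). Of the erythrocyte genes, 4 of 9 rose and 0 fell (9 and 0 adjusted over the list alone). Erythrocyte genes had a median log2 fold change of 2.07 (camera adjusted p = 0.00913, and adjusted p = 0.538 with an estimated correlation). nt5c2l1 (2.45 ± 0.27, adjusted p = 0.000463) was first by adjusted p. Without mutant tumor replicate 3 the mean log2 fold change was 1.74 in place of 2.65 for the neutrophil list and 1.23 in place of 2.58 for the erythrocyte list. Of the fibroblast and meningeal genes, 8 of 18 rose and 0 fell (11 and 0 adjusted over the list alone). Fibroblast and meningeal genes had a median log2 fold change of 1.45 (camera adjusted p = 0.000144, and adjusted p = 0.476 with an estimated correlation). Examples were the matrix genes FN1 (ENSDARG00000019815, 2.90 ± 0.16, adjusted p = 0.000156), col1a1a (6.03 ± 1.1, adjusted p = 0.0032) and COL1A2 (4.76 ± 0.87, adjusted p = 0.00364). Of the skeletal muscle genes, 6 of 12 rose and 0 fell (7 and 0 adjusted over the list alone). Skeletal muscle genes had a median log2 fold change of 2.49 (camera adjusted p = 0.0299, and adjusted p = 0.538 with an estimated correlation). pvalb2 (4.94 ± 1.1, adjusted p = 0.00746) and actc1b (3.92 ± 0.94, adjusted p = 0.0123) were first by adjusted p. This list call was lost without mutant tumor replicate 3 (adjusted p = 0.0526). Of the ependymal and cilia genes, 4 of 13 rose and 0 fell (4 and 0 adjusted over the list alone). Ependymal and cilia genes had a median log2 fold change of 0.69 (camera adjusted p = 0.0311, and adjusted p = 0.538 with an estimated correlation). The tubulin tuba5 (4.14 ± 0.55, adjusted p = 0.000949) and the ciliary regulator FOXJ1 (2.02 ± 0.28, adjusted p = 0.000991) were first by adjusted p. The call for the list did not hold without mutant tumor replicate 2 or 3 or control replicate 1 (adjusted p up to 0.0829). Of the radial glia genes, 8 of 22 rose and 1 fell (8 and 2 adjusted over the list alone). Radial glia and neural stem genes had a median log2 fold change of 0.63 (camera adjusted p = 0.0451, and adjusted p = 0.52 with an estimated correlation). Glutamine synthetase GLUL (ENSDARG00000100003, 0.99 ± 0.12, adjusted p = 0.000654) and the receptor NOTCH1 (ENSDARG00000103554, 1.66 ± 0.28, adjusted p = 0.00256) were among the rises. The radial glia call was lost without mutant tumor replicate 3 or control replicate 2 or 3 (adjusted p up to 0.0579). Of the Group 4 medulloblastoma marker genes, 1 of 17 rose and 8 fell (1 and 9 adjusted over the list alone). Group 4 medulloblastoma marker genes had a median log2 fold change of -0.56 (camera adjusted p = 0.0133, and adjusted p = 0.216 with an estimated correlation). The falls included the synuclein SNCG (ENSDARG00000109715, -0.89 ± 0.14, adjusted p = 0.00181) while the homeobox gene OTX2 (1.63 ± 0.21, adjusted p = 0.000732) rose.

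The largest rises named here leave out 5 genes with clone names. The perforin prf1.8 was absent from all 3 controls and at least 338-fold higher in mutant tumors, against a floor of 3 counts over the control group, at 6.29, 11.91 and 38.26 CPM. The NK-lysin nkl.2 (8.67 ± 1.5, adjusted p = 0.00254), the collagen COL10A1 (ENSDARG00000054753, 8.03 ± 1.40, adjusted p = 0.00298) and the histone hist1h2a9 (7.53 ± 0.67, adjusted p = 0.000353) followed. COL10A1 stood at 37.86, 1.3 and 51.68 CPM in mutant tumor replicates 1, 2 and 3. The protease inhibitor spink2.7 was 171-fold higher (95% counting interval 58.1 to 830) and spink2.5 was 158-fold higher (53.8 to 768), each from 3 counts in the controls, and the spink2.5 call was lost without any 1 of the controls (adjusted p up to 0.0587, fold changes from 6.46 to 10.61). In mutant tumors spink2.7 stood at 1.43, 11.96 and 15.81 CPM and spink2.5 at 0.83, 9.72 and 16.44 CPM. The largest falls included the hypothalamic hormones oxt (-4.13 ± 0.63, adjusted p = 0.00175) and agrp (-3.95 ± 1.0, adjusted p = 0.0171), the transcription factor egr2a (-3.82 ± 0.36, adjusted p = 0.000375), the small heat shock protein CRYAB (-3.49 ± 0.89, adjusted p = 0.016), vitronectin VTN (ENSDARG00000053831, -3.21 ± 0.60, adjusted p = 0.00393) and the serotonin receptor htr7a (-3.13 ± 0.45, adjusted p = 0.00126). The agrp call was lost without control replicate 1 (adjusted p = 0.0618, fold changes from -5.05 to -2.79) and the CRYAB call without mutant tumor replicate 1 or control replicate 3 (adjusted p up to 0.0605, fold changes from -4.81 to -2.91).

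In total 3883 genes were higher and 3604 lower in mutant tumors at an adjusted p of 0.05, of which 2322 and 1450 changed at least 2-fold. The authors' deposited table held 4440 higher and 4092 lower genes, which included 3857 and 3586 of these, with no gene called in the opposite direction. The groups did not overlap for 55.7% of the genes tested, against 10% by chance. Lists that did not pass are given with genes that rose and fell, both counts adjusted over the list alone, the median log2 fold change and the camera adjusted p. p53 target genes (7 and 5 of 29, 7 and 6, 0.11, 0.938) and oligodendrocyte and myelin genes (4 and 4 of 20, 6 and 4, 0.07, 0.7) did not pass. Endothelial and mural cell genes (4 and 1 of 26, 4 and 0, 0.23, 0.524) and retina and photoreceptor genes (0 and 0 of 13, 0 and 0, -0.19, 0.549) did not pass. Skin keratin genes (2 and 0 of 10, 0 and 0, 0.89, 0.288) and WNT medulloblastoma marker genes (6 and 2 of 15, 6 and 2, 0.43, 0.371) did not pass. Group 3 medulloblastoma marker genes (2 and 5 of 9, 3 and 5, -1.15, 0.421) and RAS-MAPK target genes (2 and 9 of 20, 2 and 9, -0.47, 0.0818) did not pass. Unfolded protein and heat shock genes (6 and 2 of 20, 6 and 2, 0.69, 0.186) did not pass. The early response gene egr1 (-2.18 ± 0.33, adjusted p = 0.0016) and the phosphatase DUSP2 (-1.79 ± 0.27, adjusted p = 0.00151) fell within the RAS-MAPK list, which passed without mutant tumor replicate 2 (adjusted p = 0.0324) or control replicate 3 (0.0407), and in the p53 list the death receptor fas (2.45 ± 0.36, adjusted p = 0.00139) rose while the kinase PLK2 (ENSDARG00000019130, -1.35 ± 0.17, adjusted p = 0.00072) fell. The skin keratin list passed without mutant tumor replicate 2 (adjusted p = 0.0372). Among the myelin genes cnp (2.61 ± 0.32, adjusted p = 0.000655) and PLP1 (1.82 ± 0.36, adjusted p = 0.00498) rose and erbb3b (-1.17 ± 0.28, adjusted p = 0.0121) fell. The 4 pituitary hormone genes tested were too few for a list test, and growth hormone gh1 stood at 58.56, 0.32 and 0.58 CPM in the controls. Without control replicate 3 the number of higher genes fell to 2511, and without mutant tumor replicate 1 or 3 the number of lower genes fell to 2241 or 2327.

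**Figure D2:**
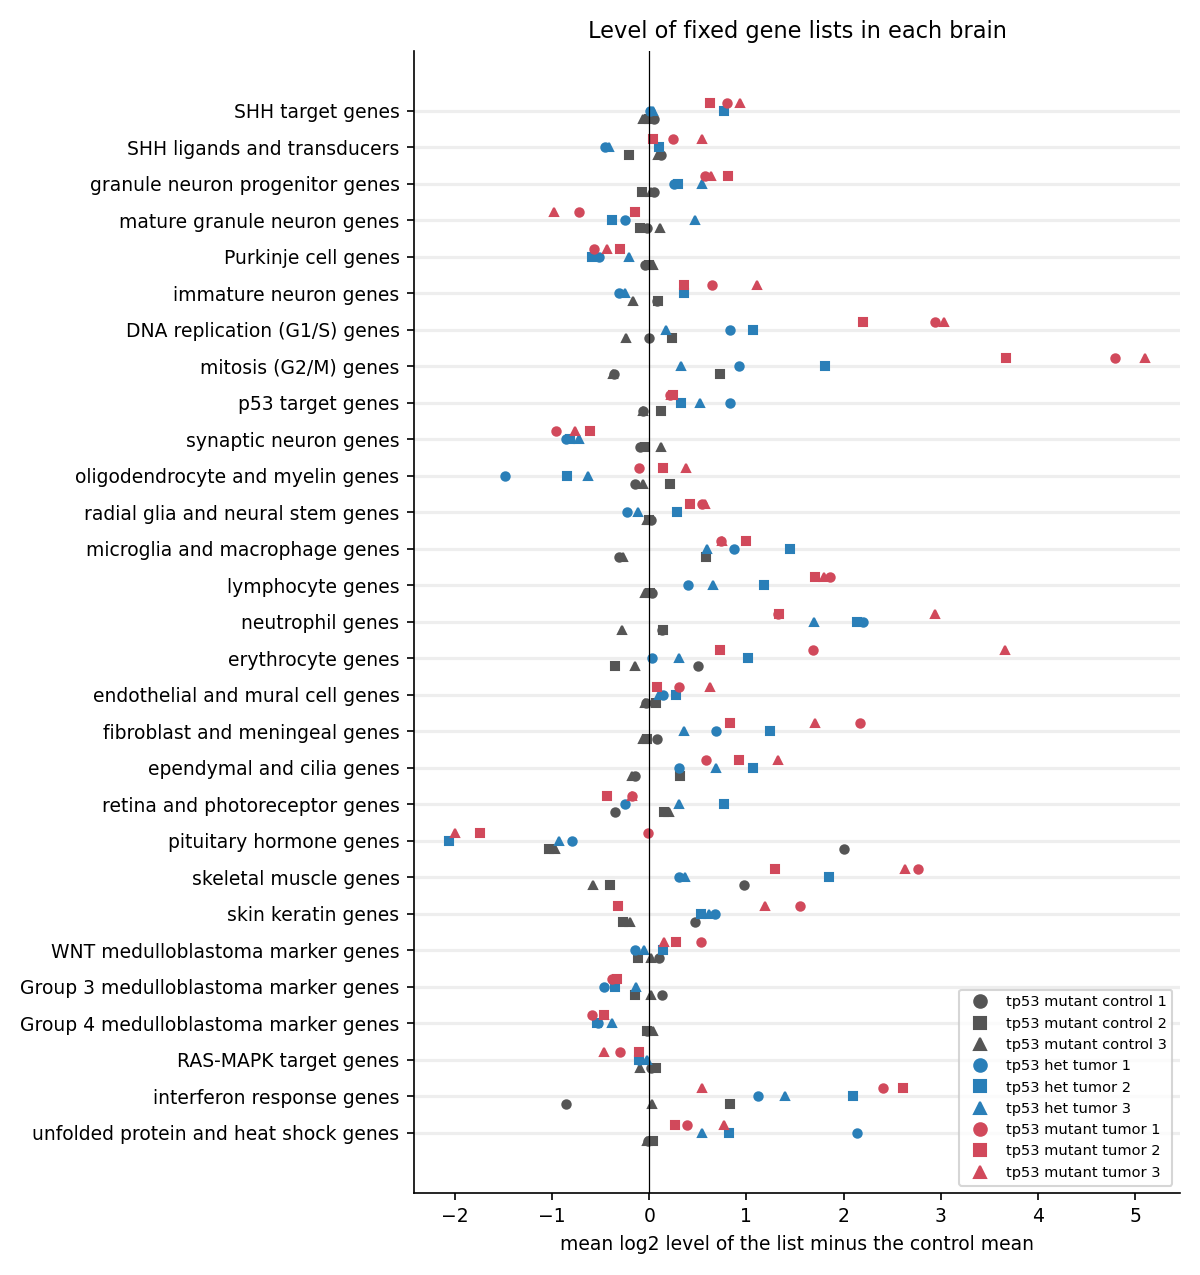
Mean log2 level of each fixed gene list in each of the 9 brains, relative to the mean of the 3 controls, with circles, squares and triangles for replicates 1, 2 and 3. Mitosis genes lay at 4.79, 3.67 and 5.10 in mutant tumors, 0.92, 1.81 and 0.33 in heterozygous tumors and -0.36, 0.73 and -0.37 in controls.

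The second comparison set the tp53 heterozygous tumor brains against the same controls. These controls were tp53 mutant, so tp53 genotype, tumor status, ptch1 disruption and age all differed here and cannot be told apart. Synaptic genes fell as a group, and 0 of 30 rose and 18 fell (0 and 20 adjusted over the list alone). Synaptic neuron genes had a median log2 fold change of -0.78 (camera adjusted p = 3.77e-12, and adjusted p = 0.464 with an estimated correlation). CAMK2A (-1.51 ± 0.13, adjusted p = 0.00042) and the vesicle fusion gene SNAP25 (ENSDARG00000020609, -1.11 ± 0.15, adjusted p = 0.00193) were among those that fell. Of the oligodendrocyte and myelin genes, 1 of 20 rose and 8 fell (1 and 11 adjusted over the list alone). Oligodendrocyte and myelin genes had a median log2 fold change of -1.04 (camera adjusted p = 0.000123, and adjusted p = 0.464 with an estimated correlation). Examples were the galactolipid enzyme UGT8 (-1.67 ± 0.27, adjusted p = 0.00332), the myelin protein gene zwi (-1.79 ± 0.31, adjusted p = 0.00509) and the receptor GPR37 (ENSDARG00000033296, -1.05 ± 0.20, adjusted p = 0.00624). Of the unfolded protein and heat shock genes, 8 of 20 rose and 0 fell (8 and 0 adjusted over the list alone). Unfolded protein and heat shock genes had a median log2 fold change of 1.24 (camera adjusted p = 2e-04, and adjusted p = 0.598 with an estimated correlation). Leading genes were the stress transcription factors DDIT3 (1.83 ± 0.25, adjusted p = 0.00214) and XBP1 (2.47 ± 0.36, adjusted p = 0.00246) and the chaperone HSPA5 (1.88 ± 0.30, adjusted p = 0.00349). Their mean level over controls was 2.14 in heterozygous tumor replicate 1, 0.82 in replicate 2 and 0.54 in replicate 3, and without replicate 1 the mean log2 fold change was 0.75 in place of 1.56. Of the p53 target genes, 12 of 29 rose and 5 fell (13 and 6 adjusted over the list alone). p53 target genes had a median log2 fold change of 0.42 (camera adjusted p = 0.0273, and adjusted p = 0.662 with an estimated correlation). The stress sensor sesn2 (3.32 ± 0.38, adjusted p = 0.00114), the death receptor fas (2.82 ± 0.37, adjusted p = 0.00171) and TP53INP1 (1.53 ± 0.21, adjusted p = 0.00202) were higher and PLK2 (ENSDARG00000090752, -1.21 ± 0.14, adjusted p = 0.00114) lower, and the list call was lost without control replicate 1 or 3 (adjusted p up to 0.0925).

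Cell division genes stood far lower than in the mutant tumors, and few passed on their own. Of the mitosis genes, 1 of 35 rose and 0 fell (0 and 0 adjusted over the list alone). Mitosis (G2/M) genes had a median log2 fold change of 1.19 (camera adjusted p = 0.00117, and adjusted p = 0.739 with an estimated correlation). The one that rose was hmmr (1.94 ± 0.58, adjusted p = 0.0397), a spindle gene whose call was lost without heterozygous tumor replicate 2 or control replicate 1 or 3 (adjusted p up to 0.131, fold changes from 1.2 to 2.41). Of the DNA replication genes, 5 of 33 rose and 0 fell (3 and 0 adjusted over the list alone). DNA replication (G1/S) genes had a median log2 fold change of 0.74 (camera adjusted p = 0.00225, and adjusted p = 0.736 with an estimated correlation). MCM3 (1.30 ± 0.20, adjusted p = 0.00292), MCM4 (2.57 ± 0.41, adjusted p = 0.00353) and UHRF1 (2.42 ± 0.41, adjusted p = 0.00408) were among those that rose. Both list calls were lost without heterozygous tumor replicate 2, at adjusted p = 0.112 for mitosis and 0.0626 for DNA replication. The mean log2 fold change of the mitosis list was 1.11, and it was 0.54 without heterozygous tumor replicate 2 and 1.69 without control replicate 2. Of the SHH target genes, 2 of 15 rose and 2 fell (2 and 2 adjusted over the list alone). The list did not pass (camera adjusted p = 0.186). MYCN rose (1.30 ± 0.10, adjusted p = 0.000256), and the mean level of the list over controls was 0.01, 0.77 and 0.04 in heterozygous tumor replicates 1, 2 and 3. Of the ligands and transducers, 4 of 18 rose and 4 fell (4 and 5 adjusted over the list alone), with SMO (1.38 ± 0.27, adjusted p = 0.00731) higher and the transmembrane gene HHATL (-2.26 ± 0.26, adjusted p = 0.0012) lower, and the list did not pass (camera adjusted p = 0.93). Of the granule neuron progenitor genes, 5 of 22 rose and 0 fell (5 and 0 adjusted over the list alone), with nhlh2 (1.49 ± 0.23, adjusted p = 0.0028) and BARHL2 (1.11 ± 0.18, adjusted p = 0.00361) as examples, and the list did not pass (camera adjusted p = 0.0742, and adjusted p = 0.0322 without heterozygous tumor replicate 1). Of the Purkinje cell genes, 0 of 19 rose and 6 fell (0 and 6 adjusted over the list alone). Purkinje cell genes had a median log2 fold change of -0.37 (camera adjusted p = 0.00225, and adjusted p = 0.464 with an estimated correlation). The calmodulin regulator PCP4 (ENSDARG00000053130, -1.12 ± 0.14, adjusted p = 0.00151) and the calcium buffer pvalb7 (-1.26 ± 0.21, adjusted p = 0.00408) were first by adjusted p.

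The microglia, neutrophil, interferon and fibroblast lists shifted upward here as well, while the lymphocyte and endothelial lists did not pass. Of the microglia and macrophage genes, 8 of 21 rose and 1 fell (8 and 1 adjusted over the list alone). Microglia and macrophage genes had a median log2 fold change of 0.61 (camera adjusted p = 0.000464, and adjusted p = 0.662 with an estimated correlation). c1qc (3.48 ± 0.29, adjusted p = 0.000329), the lipid carrier apoeb (2.51 ± 0.30, adjusted p = 0.00137) and c1qb (2.67 ± 0.34, adjusted p = 0.00162) were among the rises. Mean log2 levels of this list over the controls were 0.87, 1.45 and 0.59 in heterozygous tumors and -0.31, 0.58 and -0.27 in controls, so control replicate 2 was about level with heterozygous tumor replicate 3. The same control was the highest of the 3 controls for interferon (0.83) and mitosis genes (0.73). Of the neutrophil genes, 4 of 7 rose and 0 fell (4 and 1 adjusted over the list alone). Neutrophil genes had a median log2 fold change of 2.32 (camera adjusted p = 0.0107, and adjusted p = 0.464 with an estimated correlation). MMP9 (2.32 ± 0.37, adjusted p = 0.00348) was among those that rose. Of the interferon response genes, 6 of 22 rose and 0 fell (7 and 0 adjusted over the list alone). Interferon response genes had a median log2 fold change of 1.58 (camera adjusted p = 0.00117, and adjusted p = 0.736 with an estimated correlation). irf9 (1.05 ± 0.19, adjusted p = 0.00581) and isg15 (3.89 ± 0.73, adjusted p = 0.00708) were among the rises. Of the fibroblast and meningeal genes, 4 of 18 rose and 0 fell (5 and 0 adjusted over the list alone). Fibroblast and meningeal genes had a median log2 fold change of 0.70 (camera adjusted p = 0.00117, and adjusted p = 0.662 with an estimated correlation). Leading genes were FN1 (ENSDARG00000019815, 3.78 ± 0.17, adjusted p = 3.73e-05) and FBLN1 (3.31 ± 0.63, adjusted p = 0.00744). This list call was lost without heterozygous tumor replicate 2 (adjusted p = 0.0517). Of the ependymal and cilia genes, 4 of 13 rose and 0 fell (4 and 0 adjusted over the list alone). Ependymal and cilia genes had a median log2 fold change of 0.51 (camera adjusted p = 0.0357, and adjusted p = 0.736 with an estimated correlation). odad3 (2.35 ± 0.31, adjusted p = 0.00182) and FOXJ1 (1.73 ± 0.28, adjusted p = 0.00333) were first by adjusted p. The call for the list did not hold without heterozygous tumor replicate 2 or control replicate 1 or 3 (adjusted p up to 0.225). Of the Group 4 medulloblastoma marker genes, 1 of 17 rose and 5 fell (1 and 5 adjusted over the list alone). Group 4 medulloblastoma marker genes had a median log2 fold change of -0.39 (camera adjusted p = 0.00777, and adjusted p = 0.464 with an estimated correlation). SNCG (ENSDARG00000109715, -1.0 ± 0.14, adjusted p = 0.00214) and UNC5D (ENSDARG00000061541, -0.68 ± 0.12, adjusted p = 0.00506) were among the falls. Without heterozygous tumor replicate 2 the mean log2 fold change was 0.52 in place of 0.88 for the fibroblast list, 0.49 in place of 0.75 for the ependymal list and -0.29 in place of -0.47 for the Group 4 list, which stood at -0.27 without control replicate 3.

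The largest rises again included prf1.8, which was at least 729-fold higher than the floor of 3 counts over the controls at 11.95, 74.16 and 23.24 CPM, and nkl.2 (9.53 ± 1.40, adjusted p = 0.00298). The immunoglobulin-domain gene igfn1.2 was 333-fold higher (95% counting interval 114 to 1620), the microfibril gene mfap4.6 337-fold (115 to 1630) and spink2.7 245-fold (83.7 to 1190), each over 3 counts in the controls, and OCIAD2 (8.14 ± 1.5, adjusted p = 0.00714) completed the 6. These levels varied between animals, at 37.26, 1.74 and 19.98 CPM for igfn1.2, 2.57, 37.43 and 9.59 CPM for mfap4.6, 2.25, 26.75 and 7.34 CPM for spink2.7 and 45.99, 1.74 and 33.74 CPM for OCIAD2 in the heterozygous tumors, spread that the counting intervals leave out. Without heterozygous tumor replicate 2 the fitted log2 fold change was 6.63 in place of 8.09 for mfap4.6 and 6.29 in place of 7.65 for spink2.7, and without replicate 1 it was 7.45 in place of 8.32 for igfn1.2. The largest falls included oxt (-4.70 ± 0.66, adjusted p = 0.00224), VTN (ENSDARG00000053831, -4.23 ± 0.64, adjusted p = 0.00284) and the extracellular matrix genes acanb (-3.83 ± 0.32, adjusted p = 0.000329) and HAPLN2 (-3.71 ± 0.54, adjusted p = 0.00239). A pair of larger fitted falls each rested on 1 control, gh1 on replicate 1 (58.56 CPM) and the spliceosomal RNA rnu2 on replicate 3 (407.84 CPM). Without that control the fold changes were -2.76 for gh1 and -0.56 for rnu2, with adjusted p up to 0.204 and 0.302, and both calls were also lost without any 1 of the heterozygous tumors.

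In total 2604 genes were higher and 2319 lower in heterozygous tumors than in controls, of which 1608 and 938 changed at least 2-fold. The authors' deposited table held 3344 higher and 2860 lower genes, which included 2592 and 2310 of these, with no gene called in the opposite direction. The groups did not overlap for 41.3% of the genes tested, against 10% by chance. Other lists are given in the same way. Mature granule neuron genes (1 and 1 of 13, 1 and 1, -0.01, 0.595) and immature neuron genes (4 and 4 of 21, 4 and 5, -0.16, 0.496) did not pass. Radial glia and neural stem genes (4 and 5 of 22, 7 and 6, 0.11, 0.838) and lymphocyte genes (2 and 1 of 15, 2 and 1, 0.74, 0.44) did not pass. Erythrocyte genes (0 and 0 of 9, 0 and 0, 0.79, 0.556) and endothelial and mural cell genes (5 and 0 of 26, 5 and 0, -0.14, 0.595) did not pass. Retina and photoreceptor genes (0 and 0 of 13, 0 and 0, 0.79, 0.58) and skeletal muscle genes (1 and 0 of 12, 0 and 0, 0.63, 0.475) did not pass. Skin keratin genes (2 and 1 of 10, 3 and 2, 0.67, 0.442) and WNT medulloblastoma marker genes (0 and 2 of 15, 0 and 2, -0.08, 0.475) did not pass. Group 3 medulloblastoma marker genes (2 and 3 of 9, 2 and 4, -0.18, 0.496) and RAS-MAPK target genes (3 and 4 of 20, 3 and 4, -0.16, 0.428) did not pass. For the immature neuron, endothelial and SHH ligand lists the sign of the median was opposite to the direction of the list test. Among immature neuron genes SOX4 (ENSDARG00000004588, 2.0 ± 0.22, adjusted p = 0.000948) and SOX11 (ENSDARG00000077811, 1.69 ± 0.18, adjusted p = 0.000904) rose, and among radial glia genes GLUL (ENSDARG00000099776, 1.3 ± 0.20, adjusted p = 0.00303) rose while the glutamate transporter SLC1A2 (-2.11 ± 0.42, adjusted p = 0.00845) fell. Without control replicate 1, 2 or 3 the number of higher genes fell to 1349, 1648 or 1319 and the number of lower genes to 1317, 1409 or 1331.

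The third comparison set the tp53 heterozygous tumors against the tp53 mutant tumors, so that rises are changes toward the heterozygous tumors. The lists of cell division genes had the lowest list p-values. Of the mitosis genes, 0 of 35 rose and 35 fell (0 and 35 adjusted over the list alone). Mitosis (G2/M) genes had a median log2 fold change of -3.49 (camera adjusted p = 5.4e-35, and adjusted p = 0.382 with an estimated correlation). Examples were the survivin gene BIRC5 (-4.12 ± 0.49, adjusted p = 0.00426), UBE2C (-3.35 ± 0.40, adjusted p = 0.00431) and KIF23 (-4.04 ± 0.50, adjusted p = 0.00467). Of the DNA replication genes, 0 of 33 rose and 29 fell (0 and 30 adjusted over the list alone). DNA replication (G1/S) genes had a median log2 fold change of -1.99 (camera adjusted p = 1.18e-22, and adjusted p = 0.382 with an estimated correlation). Examples were CCNE2 (-2.47 ± 0.29, adjusted p = 0.00426), PCNA (-2.12 ± 0.25, adjusted p = 0.00426) and CDC6 (-1.66 ± 0.24, adjusted p = 0.00574). Of the immature neuron genes, 0 of 21 rose and 7 fell (0 and 10 adjusted over the list alone). Immature neuron genes had a median log2 fold change of -0.47 (camera adjusted p = 0.000344, and adjusted p = 0.633 with an estimated correlation). The microtubule regulator STMN1 (ENSDARG00000004169, -3.66 ± 0.37, adjusted p = 0.00352), SOX11 (ENSDARG00000095743, -1.35 ± 0.25, adjusted p = 0.0108) and the tubulin tubb5 (-2.62 ± 0.50, adjusted p = 0.0115) were lower. Of the mature granule neuron genes, 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone). Mature granule neuron genes had a median log2 fold change of 0.70 (camera adjusted p = 0.0331, and adjusted p = 0.655 with an estimated correlation). This list call was lost without mutant tumor replicate 3 or heterozygous tumor replicate 3 (adjusted p up to 0.223). The mean log2 fold change of the immature neuron list was -0.49 without mutant tumor replicate 3 in place of -0.79, and that of the mature granule list was 0.26 without heterozygous tumor replicate 3 in place of 0.58.

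The lists of p53 targets and of stress genes shifted toward the heterozygous tumors, although most of their genes did not pass. Of the p53 target genes, 7 of 29 rose and 2 fell (9 and 3 adjusted over the list alone). p53 target genes had a median log2 fold change of 0.40 (camera adjusted p = 0.0197, and adjusted p = 0.633 with an estimated correlation). The stress sensor SESN1 (1.23 ± 0.17, adjusted p = 0.00562) and the cell death gene bbc3 (1.52 ± 0.30, adjusted p = 0.0129) were higher and the G2-phase gene gtse1 (-2.78 ± 0.54, adjusted p = 0.0121) lower. The bbc3 call was lost without mutant tumor replicate 1 or 3 (adjusted p up to 0.0549, fold changes from 1.15 to 1.82). Of the unfolded protein and heat shock genes, 5 of 20 rose and 0 fell (5 and 0 adjusted over the list alone). Unfolded protein and heat shock genes had a median log2 fold change of 0.85 (camera adjusted p = 0.0138, and adjusted p = 0.655 with an estimated correlation). XBP1 (1.92 ± 0.35, adjusted p = 0.0104) and the heat shock factor hsf1 (0.92 ± 0.17, adjusted p = 0.0111) were higher. The call for the list did not hold without heterozygous tumor replicate 1 (adjusted p = 0.198). Without that library the mean log2 fold change was 0.18 in place of 0.99 for this list and 0.21 in place of 0.37 for the p53 target list. Of the SHH target genes, 1 of 15 rose and 1 fell (1 and 1 adjusted over the list alone). The gene that rose was HHIP (0.93 ± 0.22, adjusted p = 0.0219). The list did not pass (camera adjusted p = 0.217), but this depended on heterozygous tumor replicate 2, without which the mean log2 fold change was -0.77 in place of -0.42 (adjusted p = 0.00645). CCND1 was lower in heterozygous tumors (-1.84 ± 0.46, adjusted p = 0.0264), a call lost without replicate 1 or 3 of either tumor group (adjusted p up to 0.0891, fold changes from -2.63 to -1.51), and MYCN differed by -0.26 ± 0.10 (adjusted p = 0.0823). The other tests of SHH ligands and transducers (0 and 2 of 18, 0 and 1 adjusted over the list alone, median -0.45, 0.0883) and granule neuron progenitor genes (0 and 6 of 22, 0 and 7 adjusted over the list alone, median 0.02, 0.217) did not pass, although the ligand list passed without mutant tumor replicate 2 (mean -0.71 in place of -0.53, adjusted p = 0.0452) or heterozygous tumor replicate 2 (mean -0.77, adjusted p = 0.0127), and INSM1 (ENSDARG00000091756, -2.46 ± 0.29, adjusted p = 0.00426) and HHATL (-1.92 ± 0.26, adjusted p = 0.00552) fell.

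The oligodendrocyte, radial glia, lymphocyte and erythrocyte lists shifted toward the mutant tumors, with a minority of their genes past the threshold, while the microglia and neutrophil lists did not pass. Of the oligodendrocyte and myelin genes, 0 of 20 rose and 7 fell (1 and 11 adjusted over the list alone). Oligodendrocyte and myelin genes had a median log2 fold change of -0.86 (camera adjusted p = 1.15e-06, and adjusted p = 0.384 with an estimated correlation). UGT8 (-2.50 ± 0.27, adjusted p = 0.00377), PLP1 (-2.62 ± 0.37, adjusted p = 0.00574) and the fatty acid hydroxylase FA2H (-1.25 ± 0.23, adjusted p = 0.00994) were lower in heterozygous tumors. Of the radial glia genes, 1 of 22 rose and 6 fell (1 and 7 adjusted over the list alone). Radial glia and neural stem genes had a median log2 fold change of -0.54 (camera adjusted p = 0.0346, and adjusted p = 0.633 with an estimated correlation). GLUL (ENSDARG00000099776, 1.19 ± 0.20, adjusted p = 0.00872) was higher, and S100B (-1.2 ± 0.25, adjusted p = 0.0146), FABP7 (ENSDARG00000007697, -2.15 ± 0.50, adjusted p = 0.0209) and NOTCH1 (ENSDARG00000103554, -1.15 ± 0.28, adjusted p = 0.0226) were among the 6 lower genes. These 3 falls were each lost without mutant tumor replicate 1 or heterozygous tumor replicate 3, and those of FABP7 and NOTCH1 also without mutant tumor replicate 3 or heterozygous tumor replicate 1 (adjusted p up to 0.0592, 0.0792 and 0.0815). This list call was lost without heterozygous tumor replicate 1 or 3 (adjusted p up to 0.0952). Of the lymphocyte genes, 0 of 15 rose and 3 fell (0 and 6 adjusted over the list alone). Lymphocyte genes had a median log2 fold change of -1.12 (camera adjusted p = 0.0069, and adjusted p = 0.382 with an estimated correlation). RAG1 (-3.95 ± 0.53, adjusted p = 0.00537) and the homing receptor CCR7 (-2.95 ± 0.49, adjusted p = 0.00799) were lower. Of the erythrocyte genes, 0 of 9 rose and 3 fell (0 and 5 adjusted over the list alone). Erythrocyte genes had a median log2 fold change of -1.97 (camera adjusted p = 0.0069, and adjusted p = 0.655 with an estimated correlation). nt5c2l1 (-1.64 ± 0.26, adjusted p = 0.00689) was lower. The call for the list did not hold without mutant tumor replicate 3 (adjusted p = 0.0656). Of the WNT medulloblastoma marker genes, 0 of 15 rose and 3 fell (0 and 3 adjusted over the list alone). WNT medulloblastoma marker genes had a median log2 fold change of -0.60 (camera adjusted p = 0.0475, and adjusted p = 0.633 with an estimated correlation). This list call was lost without mutant tumor replicate 1 or 2 or heterozygous tumor replicate 1 or 3 (adjusted p up to 0.118). Mean log2 fold changes moved by more than 1.5 times for 4 of these lists. Without heterozygous tumor replicate 2 they were -0.66 in place of -0.42 for radial glia, -1.86 in place of -1.23 for lymphocytes and -3.13 in place of -2.05 for erythrocytes. The erythrocyte mean was -3.2 without mutant tumor replicate 2 and -0.7 without replicate 3, and the WNT mean was -0.15 without mutant tumor replicate 1 in place of -0.28.

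The largest rises toward the heterozygous tumors that held without each library in turn were the cholesterol acyltransferase LCAT (5.22 ± 0.55, adjusted p = 0.00377), the proteoglycan prg4b (4.77 ± 0.48, adjusted p = 0.00339) and the vitamin D hydroxylase CYP24A1 (4.43 ± 0.55, adjusted p = 0.00467). The muscle ubiquitin ligase trim63a (6.17 ± 1.40, adjusted p = 0.0175), igfn1.2 (5.57 ± 1.1, adjusted p = 0.0127) and the AP-1 gene FOSL1 (4.87 ± 1.2, adjusted p = 0.0225) were also among the 6 largest. The trim63a call was lost without mutant tumor replicate 3 or heterozygous tumor replicate 1, and those of igfn1.2 and FOSL1 without mutant tumor replicate 1 or 3. Fold changes over left-out libraries ran from 4.76 to 8.24 for trim63a, 4.71 to 6.10 for igfn1.2 and 2.08 to 5.39 for FOSL1, with adjusted p up to 0.07, 0.0557 and 0.0848. FOSL1 stood at 327.49, 11.83 and 23.24 CPM in the heterozygous tumors. The largest falls included COL10A1 (ENSDARG00000054753, -6.45 ± 1.2, adjusted p = 0.0109), the bone matrix gene spp1 (-6.22 ± 1.2, adjusted p = 0.0126), the ribonucleotide reductase subunit RRM2 (ENSDARG00000020711, -5.35 ± 1.1, adjusted p = 0.0149) and the histones hist1h2a9 (-4.89 ± 0.55, adjusted p = 0.00426), h2ax2 (-4.80 ± 0.72, adjusted p = 0.0063) and histh1l3 (-4.75 ± 0.70, adjusted p = 0.00616). The COL10A1 call was lost without heterozygous tumor replicate 3, that of spp1 without heterozygous tumor replicate 1 or 3, and that of RRM2 without mutant tumor replicate 1 or 3. Their fold changes over left-out libraries ran from -7.01 to -5.82, -6.78 to -4.93 and -10.19 to -4.74, with adjusted p up to 0.0501, 0.0547 and 0.0526.

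In total 2140 genes were higher and 2236 lower in heterozygous than in mutant tumors, of which 855 and 1179 changed at least 2-fold. The authors' deposited table held 3059 higher and 3042 lower genes, which included 2135 and 2227 of these, with no gene called in the opposite direction. The groups did not overlap for 38% of the genes tested, against 10% by chance. The remaining lists follow in the same form. Purkinje cell genes (0 and 2 of 19, 0 and 0, -0.09, 0.807) and synaptic neuron genes (5 and 1 of 30, 6 and 2, 0.09, 0.472) did not pass. Microglia and macrophage genes (2 and 2 of 21, 1 and 0, 0.17, 0.531) and neutrophil genes (1 and 0 of 7, 1 and 0, -0.14, 0.807) did not pass. Endothelial and mural cell genes (1 and 1 of 26, 0 and 1, -0.03, 0.824) and fibroblast and meningeal genes (3 and 5 of 18, 5 and 7, -0.92, 0.24) did not pass. Ependymal and cilia genes (1 and 1 of 13, 1 and 1, -0.29, 0.783) and retina and photoreceptor genes (2 and 0 of 13, 1 and 0, 0.99, 0.217) did not pass. Skeletal muscle genes (0 and 0 of 12, 0 and 0, -1.59, 0.0546) and skin keratin genes (1 and 1 of 10, 1 and 1, -0.70, 0.798) did not pass. Group 3 medulloblastoma marker genes (1 and 2 of 9, 1 and 2, 0.14, 0.846) and Group 4 medulloblastoma marker genes (1 and 1 of 17, 0 and 0, -0.11, 0.807) did not pass. RAS-MAPK target genes (4 and 3 of 20, 5 and 3, 0.24, 0.395) and interferon response genes (0 and 2 of 22, 0 and 0, -0.37, 0.472) did not pass. For the granule progenitor, neutrophil and Group 4 lists the sign of the median was opposite to the direction of the list test, and the mean of the synaptic list was -0.04. In the fibroblast list FN1 (ENSDARG00000019815, 0.88 ± 0.15, adjusted p = 0.00799) rose, while COL1A1 (-3.43 ± 0.67, adjusted p = 0.0127), COL1A2 (-4.05 ± 0.83, adjusted p = 0.0141) and col1a1a (-4.44 ± 0.96, adjusted p = 0.0167) fell. These collagen calls were lost without heterozygous tumor replicate 1 or 3, and that of col1a1a also without mutant tumor replicate 1 (adjusted p up to 0.0574, 0.0619 and 0.0646). Of the lists that did not pass, several passed without a single library. The fibroblast list did without mutant tumor replicate 2 (adjusted p = 0.00074), the interferon list without mutant tumor replicate 3 (0.00121), the retina list without heterozygous tumor replicate 1 (0.0409) and the skeletal muscle list without mutant tumor replicate 2 (0.00426) or heterozygous tumor replicate 2 (0.0139). These counts moved with single libraries. Higher genes numbered 421 without mutant tumor replicate 1, 488 without mutant tumor replicate 3, 971 and 632 without heterozygous tumor replicates 1 and 3, and 3277 without heterozygous tumor replicate 2, and lower genes numbered 798, 841, 1209, 809 and 3424. With only the 2 tumor groups in the fit, 624 genes were higher and 945 lower, so most calls between the tumor groups depended on the controls being in the fit.

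None of the list calls in the 3 comparisons held when camera estimated the correlation between genes, with lowest adjusted p of 0.216, 0.464 and 0.382. The fixed lists were not fully separate, since 18% of the Group 4 genes, 13% of the WNT genes and 11% of the Purkinje cell and Group 3 genes also stood in another list, and so did 10% of the immature neuron and skin keratin genes, 7% of the SHH target genes, 5% of the RAS-MAPK genes and 3% of the p53 target genes.

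The comparisons of each tumor group with the controls were then set beside each other. Of the genes called in both, 1433 were higher in both, 1483 lower in both and 27 opposite, against 468 and 387 shared by lists drawn independently. MYCN, SMO, TP53, isg15 and the complement genes were among those higher in both, and CAMK2A, oxt and VTN among those lower in both. The log2 fold changes correlated across 21607 genes with r = 0.64, where genes are not independent replicates. Since the controls are shared, 20 simulations of unchanged groups gave r = 0.505 (range 0.484 to 0.537), and the share of genes with the same sign was 72.1% against 66.9% simulated. The covariance was 0.761 against 0.0891 simulated, a difference of 0.672. With 3 controls no split into 2 parts of at least 2 was possible, so part of the excess may come from the shared controls. Both tumor groups were also younger than these controls, a difference that the simulations left out. Agreement through age and agreement through the tumors therefore cannot be told apart. Without heterozygous tumor replicate 2 the correlation was 0.50.

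**Figure D3:**
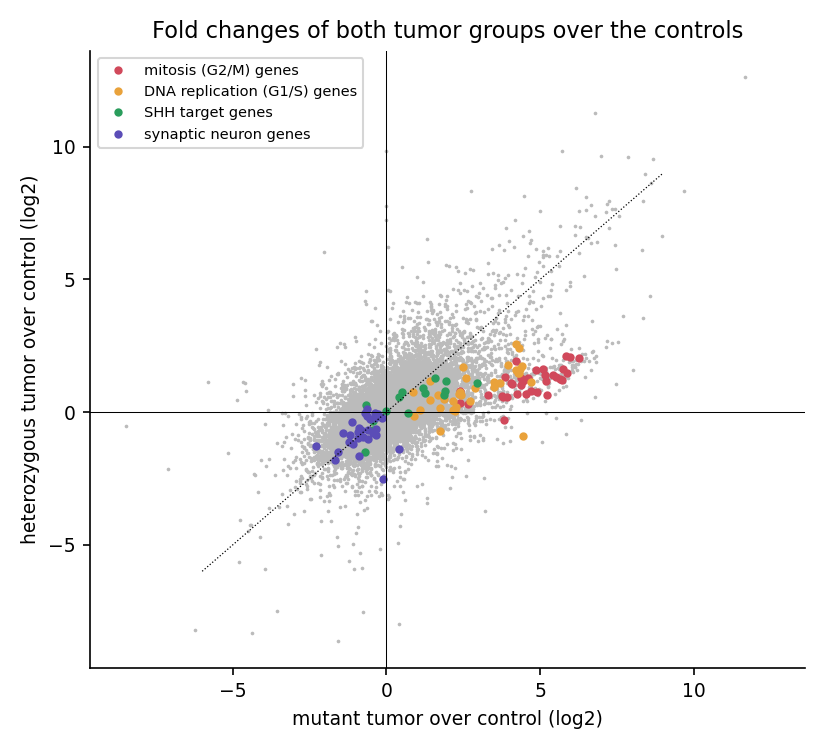
Log2 fold change over the controls in heterozygous tumors (vertical axis) against mutant tumors (horizontal axis), 1 point per gene tested, with members of 4 fixed lists in color and a dotted line of equal change. Mitosis genes had a median of 4.60 in mutant tumors and 1.19 in heterozygous tumors, while synaptic genes had medians of -0.67 and -0.78.

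A further table by the authors compared the ptch1 tumors, represented by the 3 tp53 mutant tumors, with a tumor type labelled NRAS. Its sign was read from the order of names, as in the other tables, and was not checked. The libraries of the other tumor type carry another run prefix, so tumor type and library batch cannot be told apart. In the authors' deposited table, 3976 genes were higher and 3197 lower in ptch1 tumors, of 24813 with an adjusted p. SHH target genes were mostly higher in the authors' deposited table, 10 of 15 with 2 lower, including the SHH co-receptor BOC (3.53, adjusted p = 1.39e-26), MYCN (2.99, adjusted p = 2.47e-22) and GLI1 (2.35, adjusted p = 9.6e-07), while PTCH2 (-2.34, adjusted p = 3.58e-11) and CCND2 (-3.66, adjusted p = 2.53e-10) were lower. The authors' deposited table also had 11 of 22 granule neuron progenitor genes higher and 0 lower, with INSM1 (ENSDARG00000091756, 4.46, adjusted p = 7.47e-10) and nhlh2 (4.47, adjusted p = 3.1e-07) as examples. Of 22 immature neuron genes in the authors' deposited table, 9 were higher and 0 lower, with SOX4 (ENSDARG00000098834, 4.01, adjusted p = 3.48e-47) and neurog1 (5.68, adjusted p = 1.31e-16) first. Of 29 synaptic genes in the authors' deposited table, 10 were higher and 0 lower, with GRIA2 (ENSDARG00000070173, 1.84, adjusted p = 4.93e-08) first. Genes of the oligodendrocyte lineage were lower in the authors' deposited table, 15 of 20 with 0 higher, including the lineage factors SOX10 (-6.57, adjusted p = 2.62e-61) and OLIG2 (-4.12, adjusted p = 1.1e-24). Of the 20 RAS-MAPK target genes in the authors' deposited table, 9 were lower and 4 higher, with the MAPK-induced genes ETV4 (-4.18, adjusted p = 1.06e-13) and SPRY4 (-2.47, adjusted p = 8.15e-10) lower. For cell division the authors' deposited table had 0 of 35 mitosis genes higher and 3 lower (median -0.51), and 1 of 34 DNA replication genes higher and 9 lower (median -0.52). In the authors' deposited table TP53 was lower (-1.22, adjusted p = 1.39e-08), and PTCH1 (-0.26, adjusted p = 0.721), cdkn1a (0.48, adjusted p = 0.59) and mdm2 (0.18, adjusted p = 0.589) did not pass. The other lists in the authors' deposited table, given as higher and lower genes, were SHH ligands and transducers (6 and 2 of 18), mature granule neuron genes (2 and 2 of 14), Purkinje cell genes (9 and 0 of 19), p53 target genes (8 and 4 of 29), radial glia and neural stem genes (2 and 9 of 24), microglia and macrophage genes (0 and 3 of 21), lymphocyte genes (2 and 1 of 18), neutrophil genes (1 and 0 of 7), erythrocyte genes (3 and 0 of 10), endothelial and mural cell genes (2 and 4 of 26), fibroblast and meningeal genes (1 and 6 of 19), ependymal and cilia genes (7 and 0 of 13), retina and photoreceptor genes (0 and 1 of 17), pituitary hormone genes (0 and 0 of 6), skeletal muscle genes (3 and 0 of 13), skin keratin genes (0 and 5 of 12), WNT medulloblastoma marker genes (10 and 1 of 15), Group 3 medulloblastoma marker genes (3 and 1 of 8), Group 4 medulloblastoma marker genes (4 and 3 of 19), interferon response genes (1 and 1 of 22) and unfolded protein and heat shock genes (1 and 4 of 19). The largest rises in the authors' deposited table were RPL26 (9.82), a signal recognition particle RNA copy (9.27), U2 copies (8.02 and 7.89), pcdh2ab3 (7.62) and iqcb1 (7.09), and the largest falls were GGACT copies (-9.65 and -8.47), signal recognition particle RNA copies (-7.73, -7.47 and -7.37) and ANKRD33B (-7.62). With an adjusted p under 0.01 in the authors' deposited table the counts were 2394 and 2147.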

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

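Of the tests in this part, those of swapped labels, of a larger share of the same tumor tissue, of age and of neuron loss were chosen only after the result was seen, while those of a wrong label, of skeletal tissue and of other splits were planned before it.

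For the 11 gene lists below, camera at its preset correlation called a difference between tp53 heterozygous and tp53 mutant tumors. None of the 11 passed when camera estimated the correlation between genes, with a lowest adjusted p of 0.382, and as many lists were called in 7 of the 10 splits of the same libraries. The calls for 5 lists were lost without a single library: mature granule neuron genes (0 of 13 genes past the threshold, adjusted p up to 0.223), heat shock genes (0.198), WNT marker genes (0.118), radial glia genes (0.0952) and erythrocyte genes (0.0656). The median log2 differences, heterozygous minus mutant, were -3.49 for mitosis genes, -1.99 for DNA replication genes, -1.97 for erythrocyte genes, -1.12 for lymphocyte genes, -0.86 for oligodendrocyte and myelin genes, -0.6 for WNT marker genes, -0.54 for radial glia genes and -0.47 for immature neuron genes. They were 0.85 for unfolded protein and heat shock genes, 0.7 for mature granule neuron genes and 0.4 for p53 target genes. Each tumor library was left out in turn for these lists, but why single libraries moved them was not tested.

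Splitting the same 6 libraries in all 10 ways gave too few splits for a share under 0.05. For mutant tumors against controls the real split called 7487 genes and 18 lists, and the highest other split 1 gene and 13 lists. For heterozygous tumors against controls the real split called 4923 genes and 13 lists, and the highest other split 1 gene and 14 lists. Between the tumor groups the real split called 4376 genes and 11 lists, and the highest other split 3 genes and 15 lists. As many genes were called in 1 of the 10 splits in each comparison, the real one. As many lists were called in 1, 2 and 7 of the 10 splits, so the number of lists called between the tumor groups was reached by most splits.

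Mitosis genes were higher in mutant tumors than in controls, and age differed between these groups. Age alone is argued against as the whole cause, because the lowest mutant tumor (8 weeks) stood at 3.67 in mean log2 level over controls and the highest heterozygous tumor (7 weeks) at 1.81, while the heterozygous tumors spanned 1.48. All 35 mitosis genes were higher in the 7-week mutant tumor than in each 7-week heterozygous tumor. A loss of neurons that raises all other cells alike is argued against too, since the highest median of the radial glia, oligodendrocyte, endothelial and microglia lists was 0.63 and the lower quartile of the mitosis genes was 4. Both groups were tp53 mutant. The tumor itself and an effect of age that depends on the tumor or the tp53 genotype stay open as untested explanations.

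Heterozygous tumor replicate 2 lay near mutant tumor replicate 2 (correlation 0.959), but not replicates 1 and 3 (0.936 and 0.926). Its correlations with heterozygous tumor replicates 1 and 3 were 0.942 and 0.958. A swap of labels between the tumor groups is argued against, because the lowest correlation among mutant tumors was 0.95 and the highest of a mutant tumor with heterozygous tumor replicate 1 or 3 was 0.928. A larger share of the same tumor tissue was not decided. SHH target genes stood 89.5% of the way from control to mutant tumor mean (quartiles 76.8 to 113, 7 genes). Mitosis genes stood at 8.96% (7.57 to 12.3, 35 genes) and DNA replication genes at 23%. The controls were older, and MYCN but not CCND1 had about the same level in all 3 heterozygous tumors. These percentages may therefore mix age with tumor share. A single wrong label cannot be told apart from a real difference between animals, since over 6634 genes called without it the library lay at 0.46 on a scale from 0 (mutant tumors) to 1 (other heterozygous tumors), near mutant tumor replicate 2 when that was left out (0.37) and above replicates 1 (-0.07) and 3 (-0.16). Tumors of the same genotype that differ between animals stay open as a candidate explanation.

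Collagen and bone genes were high in mutant tumor replicates 1 and 3, where COL10A1 (ENSDARG00000054753) had 1005, 29 and 1229 counts and spp1 1510, 28 and 481 counts in replicates 1, 2 and 3. Skull bone or cartilage taken with the brain was tested with 28 listed skeletal genes, of which 22 were measured. Their median log2 levels over the controls were 0.7, -0.08 and 0.8 in mutant tumors, -0.45, -0.13 and -0.53 in heterozygous tumors and -0.05, 0.05 and 0 in controls. The lower of replicates 1 and 3 lay 0.65 above the highest of replicate 2 and the controls, between the bounds of 0.5 and 1 set for the test, so skeletal tissue cannot be told apart from a change within the tumors. No biological explanation was tested for this pattern.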

How the results depend on the processing

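Of the alternatives, removal of the 4 most abundant features was chosen only after the data were seen, and all others were planned. No called gene list or named gene reversed in 1092 alternatives of list tests and 5049 of named genes, and 23 and 16 values that had not passed changed sign. Counts of called genes stayed within 1.5 times under DESeq2 size factors, both other filters, the DESeq2 test and the removal of abundant, ribosomal or mitochondrial features.

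With libraries left out in turn, the genes higher and lower in mutant tumors than in controls ranged from 2511 to 3828 and from 2241 to 3481. In heterozygous tumors against controls they ranged from 1319 to 2790 and from 1317 to 2473. Between the tumor groups they ranged from 421 (without mutant tumor replicate 1) to 3277 (without heterozygous tumor replicate 2) higher and from 798 to 3424 lower under the same omissions. Each such fit had fewer libraries. Lists called ranged from 14 to 19, 9 to 14 and 8 to 14 in the 3 comparisons. The correlation of the tumor-versus-control comparisons ranged from 0.5 without heterozygous tumor replicate 2 to 0.69 without control replicate 2. With only the tumor groups in the fit, 624 genes were higher and 945 lower, from fewer libraries to estimate the spread.

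With an estimated correlation camera called 0 lists in each of the 3 comparisons, against 18, 13 and 11 with the preset correlation. The fry test called 15 lists in mutant tumors against controls, 13 of them shared. It lost the microglia (adjusted p = 0.061), skeletal muscle (0.061), interferon (0.0645), erythrocyte (0.0645) and mature granule neuron (0.0874) lists and added the Group 3 (0.0156) and RAS-MAPK (0.0341) lists. In heterozygous tumors against controls it called 6 lists, 5 of them shared. It lost the p53 target (0.0605), fibroblast (0.0605), unfolded protein (0.0605), microglia (0.0655), ependymal (0.0888), DNA replication (0.124), interferon (0.124) and mitosis (0.216) lists and added granule neuron progenitor genes (0.0257). Between the tumor groups it called 6 lists, all 6 shared, and lost the WNT (0.0632), p53 target (0.0928), erythrocyte (0.164), unfolded protein (0.178) and mature granule neuron (0.202) lists. The cause was not tested. In the authors' deposited table of ptch1 tumors against the NRAS type, 2394 genes were higher at an adjusted p under 0.01, since the threshold is stricter. No paired analysis was possible because the replicate numbers do not tie animals across groups.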

Other observations

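The values in this part were chosen only after they were seen. Of the zebrafish copies of RRM2, a ribonucleotide reductase subunit, the first (ENSDARG00000020711) had 937, 308 and 1128 counts in mutant tumors, 51, 1 and 0 in heterozygous tumors and 35, 31 and 16 in controls. The second copy (ENSDARG00000078069) had 868, 289 and 972 counts in mutant tumors, 58, 208 and 50 in heterozygous tumors and 37, 24 and 17 in controls.

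The second deposited count table repeats the 3 mutant tumor libraries. Over 24312 shared genes, 66, 67.6 and 67.1% of the counts were identical in replicates 1, 2 and 3, and 97.5, 97.7 and 97.8% were within 5%.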
